A study of Homo sapiens with 12 samples.

How the data were processed

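Extracellular vesicles were isolated from HepG2-conditioned medium with an exosome isolation reagent, RNA of 18 nt or longer was extracted, and libraries were sequenced as single-end 50 bp reads on an Illumina HiSeq instrument, per the labels' protocols. The cells had been seeded at 300000 per well. The deposited table holds raw whole-number counts per entry and library, not normalized, for 12 libraries. Its row names end in mature (975 rows), unannotated (81), precursor (46) or stemloop (22), for 1124 rows in all, and they carry the human species prefix. The aligner, the counting tool, the miRNA annotation and the treatment of the arms of a precursor are not given in the sources used here. The submitters' processing notes name the builds GRCm38 and mm10, which are mouse builds, although the cells and the row names are human. Per the labels' protocols a 3' mRNA-seq kit was used, although the design text speaks of microRNA. How these points bear on the counts could not be settled, and a read that fits several copies of a miRNA may have been counted for any or all of them.

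Libraries were grouped by the treatment label. Within a group they are numbered in accession order, and the number pairs nothing. The numbers in the titles run from 1 to 12, and each of the ranges 1 to 6 and 7 to 12 holds 3 libraries of each group. Within each range every Control number comes before every PFAS number. If the numbers follow an order of handling, that order cannot be told apart from treatment. No pair of libraries was identical or agreed within sampling noise: the chi-square per degree of freedom was at least 118.5. Spearman's rho across tested entries had a median of 0.656 within Control, 0.728 within PFAS and 0.429 between groups; entries are not independent replicates. For libraries of a group whose title numbers differ by 6 the median was 0.689.

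Differential abundance was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM factors, a robust quasi-likelihood fit on group alone and a two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over the 362 entries kept (353 mature, 9 of other kinds). The log2 fold change is PFAS over Control, and its SE was taken as the size of the fold change over the square root of F. CPM values use TMM library sizes, so rose and fell describe a level relative to the other entries of a library, not an amount of RNA. For entries with no Control count the bound is the pooled PFAS level over that of 3 counts in all Control libraries together; for 1 to 3 counts an exact 95% interval is given. Lists were tested with camera and fry of limma 3.58.1 on log2 CPM with a prior count of 2. DESeq2 1.42.0, limma-voom and a surrogate variable from sva 3.50.0 were alternatives. Library measures were compared with exact permutation tests over all arrangements; equal depth means thinning to 262771 counts, averaged over 100 draws (20 draws for the shares of zero counts and of entries kept after thinning). Positions, 1-based, come from GENCODE release 29 on GRCh38 by gene name, since the table has none; 83 of 85 named entries matched. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

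The procedures were tested on simulated counts for PFAS against Control. With the dispersion of the real entries, over 387 entries, edgeR recovered 0 of 17 changes of 2-fold, 1 of 14 of 4-fold, 9 of 19 of 8-fold and 13 of 18 of 16-fold, and 2 of 25 calls (8%) were false. In the same simulation 5 of 41 calls (12.2%) were false with DESeq2 and 3 of 26 (11.5%) with limma-voom. Calls gained only with these 2 tools carry that limit. With a dispersion of 0.1, over 466 entries, edgeR recovered 13 of 22 of 2-fold and all 17 of 4-fold. Small changes in variable entries are therefore mostly out of reach. At a dispersion of 0.1 the rule for jumps found 39 of 40 planted jumps. With the let-7 list raised 4-fold, camera called it and none of the other lists. That run also used a lower dispersion than the 1.14 common to the real entries. Neither run therefore shows how often jumps or shifted lists would be missed at the real spread.

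Chosen before the data were examined were the tests, the 18 lists, the settings compared (other than those below) and the rule for named entries. Named are the 10 entries with the highest and the 10 with the lowest log2 fold change among those that passed, the 10 with the highest mean CPM, miR-122, miR-21, miR-192 and let-7a, and in each list up to 4 tested members with the smallest unadjusted p. Lists match the precursor name because the table gives no arms. Chosen after seeing the data were the rule for jumps, the leaving out of entries with a jump, the merging of copies, the restriction to mature entries, the thinning of all libraries before the test, and the restriction to precursors with a single mature product. The list of those precursors (47 of them tested) was written from background knowledge, after the most abundant entries had been seen, and it was not checked against a miRNA database. Entries named only as examples of jumps or of copies were chosen after their values were seen.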

Results

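Small RNA was sequenced from extracellular vesicles, the membrane-bound particles that cells release, isolated from medium conditioned by HepG2 cells, an established human liver cell line derived from a liver tumour. The cells had been kept for 24 h in 2 mL of medium with a mixture of 3 per- and polyfluoroalkyl substances (PFAS), namely PFHxA, PFOA and PFOS at 35 uM each, or with 0.1% methanol as the vehicle control. The labels give 6 PFAS and 6 Control libraries. Each library is 1 column of counts over 1124 entries, of which 975 are mature miRNA entries. An entry is named by its hairpin precursor, such as miR-30d, and gives no arm (5p or 3p), so each value may belong to either arm or to both. The treatment protocol speaks of triplicates while each group has 6 libraries. It is not known which libraries came from separate cultures, and the p-values below measure only the spread between these libraries, which may be technical.

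The PFAS libraries held more counts and more different miRNAs than the Control libraries. The total was 1797710 ± 577160 counts in PFAS (SD, n = 6, range 1156672 to 2723024) and 352446 ± 90049 in Control (SD, n = 6, range 262771 to 513298), a ratio of 5.10 (exact permutation test, two-sided, p = 0.00216, the smallest that 6 libraries against 6 can give). With each library thinned to 262771 counts, 628.5 ± 35.6 entries had at least 1 count in PFAS and 333.3 ± 20.3 in Control (SD, n = 6 each, exact permutation p = 0.00216, two-sided). With at least 5 counts asked for, the numbers were 366.3 ± 14.2 and 304.4 ± 23.6 (SD, n = 6 each, exact permutation p = 0.00216, two-sided), a ratio of 1.20 in place of 1.89. miR-146a, a miRNA known to be induced by NF-kB signalling and the entry with the highest mean level over the 12 libraries, took 28.6% ± 3.52 of the counts in PFAS and 13.2% ± 1.46 in Control (SD, n = 6 each, exact permutation p = 0.00216, two-sided). In each of the 6 Control libraries miR-92a-2 was higher than miR-146a, with a mean of 190681 CPM against 135190 CPM. The 10 most abundant entries together took 75.3% ± 5.24 in PFAS and 70.9% ± 2.23 in Control (SD, n = 6 each), a difference that did not pass (exact permutation p = 0.0801, two-sided). That difference did pass without PFAS replicate 2 (5.96 percentage points, exact permutation p = 0.0260) and without PFAS replicate 4 (5.61 percentage points, exact permutation p = 0.0390).

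**Figure D1:**
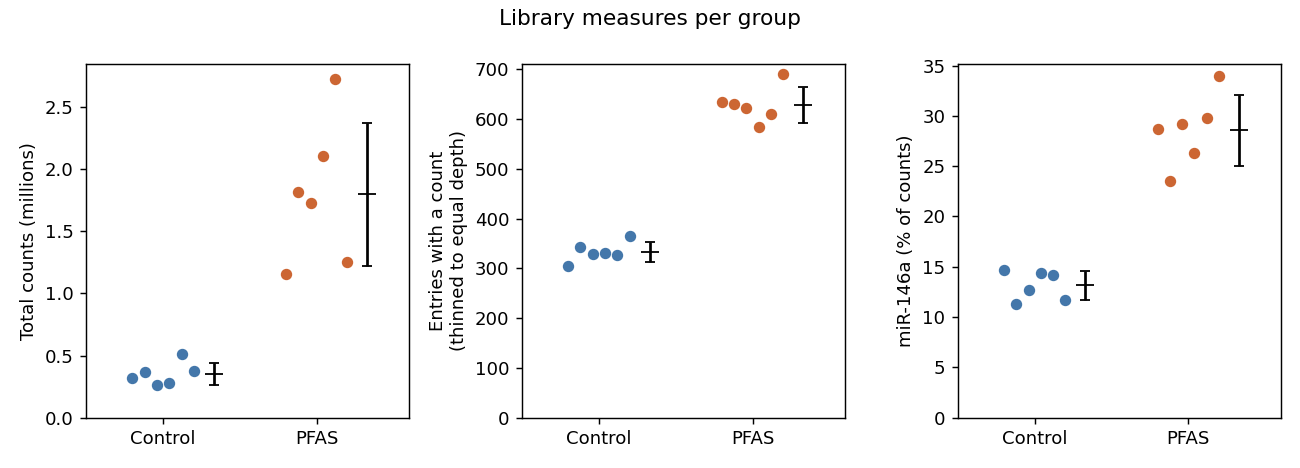
Total counts, entries with at least 1 count after thinning to equal depth, and the share of miR-146a in each of the 6 Control and 6 PFAS libraries. Points are libraries, and the bar beside them gives the mean and SD; the lowest PFAS total, 1156672, lies above the highest Control total, 513298.

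The first comparison asked which vesicle miRNAs differed after exposure to the mixture. miR-30d, miR-483, miR-629, miR-20a and let-7e were far lower in PFAS than in Control, while miR-146a, miR-429, miR-106b, miR-148a and miR-194-1 were higher. Because the entries give no arm, large changes such as the fall of miR-30d or the rise of miR-192 may reflect a different arm in each group. The last part describes this. Of 362 tested entries, 97 changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test: 48 rose, 49 fell and 265 did not pass. Among those that changed, 21 fell by more than 16-fold. Of those that rose, 3 with Control counts rose by more than 16-fold, and 9 of the 10 with no Control count had a lower bound above 16-fold. The 2 groups of libraries did not overlap in 70 of the 362 tested entries, where chance gives 0.216% of unselected entries. Entries with no Control count, such as the 10 that rose, passed the filter only through all 6 PFAS libraries. Their lack of overlap was therefore set in advance, and entries are not independent of each other. Leaving out a Control library raised the number that rose to 82, 81, 83, 85, 80 and 84 for Control replicates 1 to 6, with 423 to 428 entries then tested, and leaving out PFAS replicate 2 lowered the number that fell to 32. The number that rose was 95 with limma-voom, and the number that fell was 20 and 19 within the libraries with title numbers 1 to 6 and 7 to 12.

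**Figure D2:**
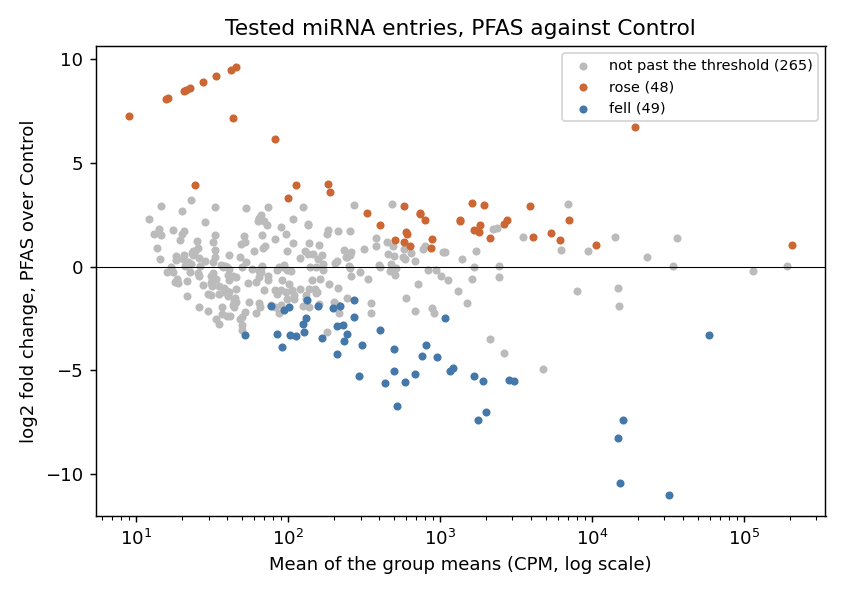
Log2 fold change of each of the 362 tested entries (PFAS over Control) against the mean of the 2 group means in CPM, on a log axis. The 48 entries that rose are orange, the 49 that fell are blue and the 265 that did not pass are grey; the straight line of points at the upper left holds entries with no Control count, whose fitted fold change depends on the prior count.

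miR-30d had the lowest fold change of all tested entries. Its level was 31.0 ± 14.6 CPM in PFAS and 64140 ± 8785 CPM in Control (SD, n = 6 each), a log2 fold change of -11.01 ± 0.44 (SE, adjusted p = 2.29e-09). MIR30D lies on chromosome 8 at 134804876 to 134804945 of GRCh38, on the minus strand, with no host gene annotated on that strand. miR-629, in an intron of TLE3 on chromosome 15 at 70079372 to 70079468, fell to 30.5 ± 17.8 CPM from 3969 ± 803 CPM (log2 fold change -7.02 ± 0.54). miR-20a, a member of the growth-promoting miR-17-92 cluster in an exon of MIR17HG on chromosome 13 at 91351065 to 91351135, fell to 24.6 ± 5.83 CPM from 1155 ± 369 CPM (log2 fold change -5.55 ± 0.37). miR-29a, of a family known to repress collagen genes, had a log2 fold change of -10.45 ± 1.20, with Control replicate 2 at 124.5 CPM against a Control mean of 30682 CPM. miR-224, in an exon of GABRE, had -8.29 ± 1.11, with Control replicate 3 at 148.4 CPM against a Control mean of 29604 CPM. The calls of miR-29a and miR-224 were lost with limma-voom (adjusted p = 0.201 and 0.112). The other 5 with the lowest fold changes, miR-197, miR-24-1, miR-29b-2, miR-30c-1 and miR-183, had 1 to 3 Control libraries at least 16-fold below the rest, and their log2 fold changes lay between -7.42 and -5.52. Of these, miR-197, miR-24-1, miR-30c-1 and miR-183 were not called with limma-voom (adjusted p = 0.0863, 0.487, 0.395 and 0.282). miR-30c-1 was also not called without PFAS replicate 2, 3, 4 or 5 (adjusted p = 0.0626, 0.0515, 0.0613 and 0.0547).

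The 10 entries with the highest fold changes had no count in any Control library. Against a floor of 3 counts over the 6 Control libraries together, miR-891a was at least 62.8-fold higher in PFAS, miR-372 at least 55.7-fold, miR-888 at least 47.4-fold, miR-9903 at least 40.8-fold and miR-3115 at least 31.1-fold. The bounds were 28.8-fold for miR-103a-2, 27.6-fold for miR-1287, 20.9-fold for miR-548v, 20.03-fold for miR-4511 and 12.4-fold for miR-3684. Their PFAS levels were low, from 18.0 ± 2.84 CPM for miR-3684 to 91.2 ± 38.7 CPM for miR-891a (SD, n = 6). miR-891a and miR-888 lie near each other on chromosome X, at 146027794 to 146027872 and 145994784 to 145994860, and miR-372, of a cluster known from embryonic stem cells, lies on chromosome 19 at 53787890 to 53787956. miR-3115 lies in an intron of KDM1A and miR-103a-2 in an intron of PANK2. Floors and intervals cover counting error only. Whether molecular identifiers were used is not known, and reads amplified without them are not independent molecules.

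Among the most abundant entries, miR-146a rose and miR-483 fell. miR-146a, in an exon of MIR3142HG on chromosome 5 at 160485352 to 160485450, reached 280873 ± 26287 CPM in PFAS and 135190 ± 20754 CPM in Control (SD, n = 6 each, log2 fold change 1.05 ± 0.11, adjusted p = 2.64e-05). miR-483, in an intron of the insulin-like growth factor gene IGF2 on chromosome 11 at 2134134 to 2134209, fell to 10979 ± 2034 CPM from 107479 ± 15486 CPM (log2 fold change -3.29 ± 0.17, adjusted p = 2.09e-08). miR-30e rose to 38182 ± 19618 CPM from 352.6 ± 72.8 CPM (log2 fold change 6.76 ± 0.72, adjusted p = 2.64e-05), with PFAS replicate 4 at 1408 CPM, and was not called with limma-voom (adjusted p = 0.483). miR-92a-2, miR-423, miR-128-2, miR-484 and miR-186 did not pass, with log2 fold changes of 0.01 ± 0.12, -0.21 ± 0.13, 0.03 ± 0.13, 0.48 ± 0.19 and 1.36 ± 1.38. miR-92a-2 and miR-128-2 were below 0 without PFAS replicate 3 or 5, down to -0.077 and -0.049. miR-423 was above 0 without Control replicate 1, 3, 4, 5 or 6 or without PFAS replicate 1, 2 or 4, up to 0.13, and it passed at -0.59 with all libraries thinned to the smallest total (adjusted p = 0.00445). miR-186 was at -2.16 with limma-voom, and it passed at 2.31 within title numbers 1 to 6 (adjusted p = 0.00818) and at 1.79 with title numbers 6 apart summed (adjusted p = 0.0120). miR-484 passed with each other scaling that was tried (adjusted p from 0.0168 to 0.0473) and without any 1 of the Control libraries or without PFAS replicate 1, 2 or 4 (adjusted p from 0.00473 to 0.0114). The median log2 fold change of all tested entries was -0.08 with all libraries. It lay between 0.13 and 0.28 without any 1 Control library or without PFAS replicate 1, 2 or 4. Without PFAS replicate 3, 5 or 6 it lay between -0.18 and -0.06. Small fold changes move with this median, so these changes do not single out the library left out. miR-186 was at 4.46 CPM in its lowest PFAS library and 85970 CPM in its highest.

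**Figure D3:**
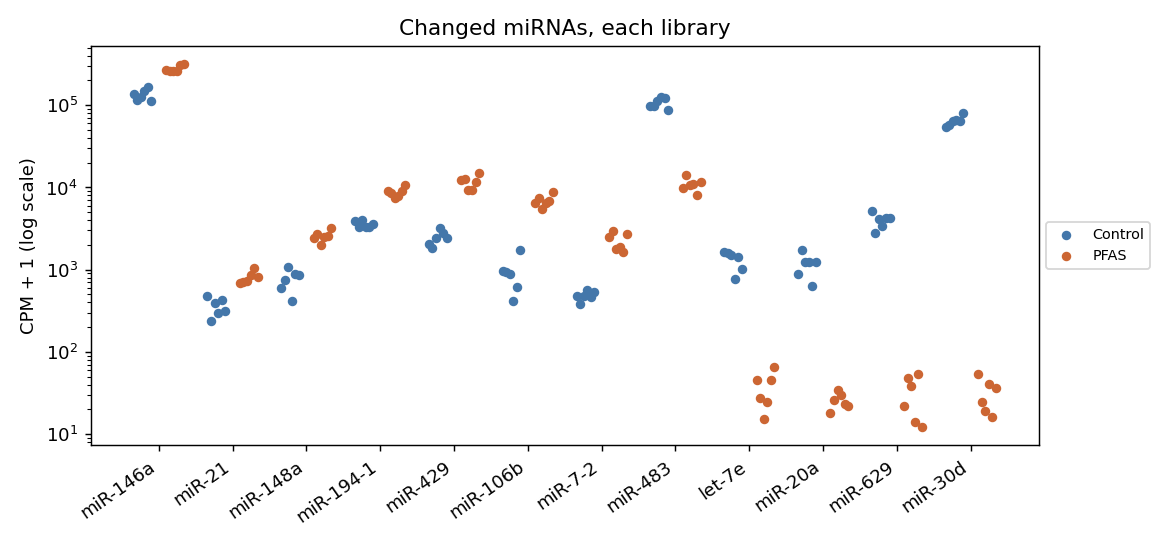
Level in CPM plus 1, on a log axis, of 12 entries that changed, with 1 point per library (6 Control in blue, 6 PFAS in orange). The groups do not overlap for any of the 12.

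Of the miRNAs named in advance, miR-122, the most abundant miRNA of normal hepatocytes, did not pass: its level was 4952 ± 5400 CPM in PFAS and 11109 ± 2509 CPM in Control (SD, n = 6 each, log2 fold change -1.17 ± 1.36, adjusted p = 0.600). miR-122 ranged from 2.62 to 10276 CPM in the PFAS libraries, and it passed with limma-voom (log2 fold change -4.77, adjusted p = 0.0322, where the adjusted p over all settings ran from 0.0322 to 0.909). miR-21, often raised in tumours and in liver injury, rose to 806.3 ± 131.8 CPM from 355.7 ± 89.7 CPM (log2 fold change 1.18 ± 0.27, adjusted p = 0.00469). miR-192, a liver-enriched miRNA, rose to 161.5 ± 61.6 CPM from 2.39 ± 4.57 CPM (log2 fold change 6.15 ± 1.05, adjusted p = 0.000844). Its precursor is not on the list of those with a single mature product, so this rise may also reflect a different arm in each group. The 3 precursors of let-7a, a tumour-suppressing miRNA, gave different results although they yield the same 5p product. let-7a-2 rose (log2 fold change 2.04 ± 0.37), let-7a-1 fell (-2.83 ± 0.96, adjusted p = 0.0443) and let-7a-3 did not pass (-1.95 ± 1.07), with 0.59 without Control replicate 1. The call of let-7a-1 was lost without any 1 of the PFAS libraries or without Control replicate 1, 2 or 5 (adjusted p from 0.0568 to 0.137), and with limma-voom (adjusted p = 0.259).

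The second comparison asked whether 18 lists of miRNAs, fixed before the data were examined, differed as groups. None of the 17 lists with at least 4 tested members passed in camera with a preset correlation of 0.01, the lowest adjusted p being 0.498, and none passed with an estimated correlation, the lowest adjusted p being 0.748. At an unadjusted p under 0.05, 1 list passed with the preset correlation (blood cell and serum miRNAs, p = 0.0293) and 0 with the estimated 1. fry, which does not compare a list with other entries, gave 8 lists with an adjusted p under 0.05 for movement on balance in 1 direction and 13 for change in either direction. Counts below are over all entries tested, and with p adjusted over the list alone they were the same unless stated.

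Of 8 hepatocyte-enriched miRNAs, 4 rose and 2 fell, with 3 that fell when adjusted over the list alone. miR-148a rose to 2569 ± 412 CPM from 764.2 ± 234.6 CPM (log2 fold change 1.75 ± 0.29), and miR-194-1, which is made with miR-215 from chromosome 1, rose to 8792 ± 1166 CPM from 3577 ± 324 CPM (1.30 ± 0.23), while its copy miR-194-2 did not pass (-2.23). miR-192 and miR-483, given above, belong to this list too. Of 12 lipid and PPAR-alpha related miRNAs, 5 rose and 2 fell. miR-106b, in an intron of MCM7, rose (2.91 ± 0.38) and miR-26a-2, in an intron of CTDSP2, fell (-3.77 ± 0.41), while its copy miR-26a-1 did not pass (3.02). miR-27a had a single count in the Control libraries, and its level in PFAS was 187.4 times that in Control (95% exact counting interval 33.6 to 7410). The median log2 fold change of this list was 1.46, also with miR-103a-2 placed at its bound. Of 15 miRNAs of liver injury, fibrosis and inflammation, 2 rose (miR-146a and miR-21) and 4 fell, with 6 that fell when adjusted over the list alone, and 7 of the 15 had a within-group jump of at least 16-fold.

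In the let-7 family 2 of 12 entries rose and 2 fell, with let-7i up (2.95 ± 0.52) and let-7e down (-5.18 ± 0.45), from 1324 ± 347 CPM in Control to 36.4 ± 18.6 CPM in PFAS. In the miR-17-92 cluster and its paralogs 2 of 11 rose (miR-106b and miR-19b-2) and 1 fell (miR-20a), with 2 that fell when adjusted over the list alone. miR-19b-2 (1.33 ± 0.41) was not called without PFAS replicate 6 (adjusted p = 0.0546), and its call was lost in 6 of 29 settings (adjusted p up to 0.328). In the same list miR-25, in an intron of MCM7 like miR-106b, did not pass (-3.50 ± 1.27). It passed without Control replicate 2 or 4 (log2 fold change -3.59 in both) and was at 0.29 without Control replicate 6. In the miR-30 family 1 of 5 entries rose (miR-30e) and 3 fell, among them miR-30d and miR-30b (-5.27 ± 1.59). miR-30c-1, which also fell, lies in an intron of NFYC, as does miR-30e. miR-30b was not called without Control replicate 2 or without PFAS replicate 1, 2, 5 or 6 (adjusted p = 0.0518, 0.0513, 0.0626, 0.0547 and 0.0514) or with limma-voom (adjusted p = 0.225), and 3 of the 5 had a within-group jump.

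In the miR-15/16 family 1 of 4 entries rose, miR-16-2 (1.45 ± 0.29), while miR-16-1 (1.42 ± 1.05), miR-15a (-1.22 ± 0.84) and miR-15b (0.12 ± 0.59) did not pass. miR-16-1 passed with title numbers 6 apart summed (adjusted p = 0.0269). In the miR-23/27/24 clusters 1 of 6 rose (miR-27a) and 1 fell (miR-24-1), with 2 that fell when adjusted over the list alone. miR-24-2 did not pass (-4.95 ± 1.89), passed without Control replicate 5 (-4.97, adjusted p = 0.0455) and was at 1.38 without Control replicate 2. miR-23b did not pass (0.68 ± 0.33) and passed without Control replicate 1 (adjusted p = 0.0334). In the epithelial list 3 of 5 entries rose and 1 fell. This list joins miR-203a to the miR-200 family, which marks epithelial cells. Of the family, miR-200a did not pass (-0.23 ± 0.84), and the entry that fell was miR-203a. miR-429 rose to 11688 ± 2269 CPM from 2456 ± 502 CPM (2.25 ± 0.27, adjusted p = 4.95e-05), its neighbour miR-200b on chromosome 1 rose (1.68 ± 0.33) and miR-200c rose (3.58 ± 1.14). miR-200c was not called without PFAS replicate 5 or 6 (adjusted p = 0.0527 and 0.0542). miR-203a fell (-1.90 ± 0.63), and its call was lost without any 1 library except Control replicate 6 and PFAS replicate 6 (adjusted p from 0.0544 to 0.152), and with total-count scaling (adjusted p = 0.0569) or RLE factors (adjusted p = 0.0508). None of the 6 entries of the miR-181 family and none of the 4 of the miR-320 family changed in edgeR, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. miR-181b-2 had a log2 fold change of 1.72 ± 0.97, passing at 1.95 with title numbers 6 apart summed (adjusted p = 0.0357), and miR-320d-2 of 0.57 ± 0.63. The sign of miR-320c-1 and miR-320c-2 (-0.18 ± 0.53 and -0.00 ± 0.42) and of miR-320d-1 (0.04 ± 0.66) changed when single libraries were left out, over -0.25 to 0.36, -0.069 to 0.38 and -0.17 to 0.92.

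Of 21 vesicle-associated miRNAs, 4 rose and 2 fell. miR-99b rose (1.40 ± 0.28) from 1168 ± 345 CPM to 3073 ± 297 CPM, miR-151a, in an intron of PTK2, rose (2.94 ± 0.65) and miR-451a fell (-1.98 ± 0.48). The call of miR-151a was lost in 2 of 29 settings (adjusted p up to 0.122) and that of miR-451a in 3 of 29 (adjusted p up to 0.313). Of 12 entries of the 14q32 imprinted cluster, 0 rose and 1 fell, miR-369 (-1.61 ± 0.33, lost in 3 of 29 settings, adjusted p up to 0.149), with 1 at an unadjusted p under 0.05, 1 called by DESeq2 and 3 by limma-voom. None of 6 entries of the chromosome 19 primate cluster changed in edgeR, with 0 at an unadjusted p under 0.05, 0 called by DESeq2 and 3 by limma-voom. In that cluster miR-522 (2.68 ± 1.28) passed without Control replicate 6 (adjusted p = 0.00156) and miR-516a-2 (0.50 ± 1.38) without Control replicate 1 (adjusted p = 0.000755). These were the only Control libraries with counts of them (12 and 31), and against 3 counts over the other 5 the PFAS levels were at least 19.7-fold and 12.7-fold higher.

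Among markers of other cell types and of serum, 1 of 4 blood cell entries fell, miR-451a, the main red-cell miRNA, at 80.1 ± 39.7 CPM in PFAS and 316.8 ± 128.0 CPM in Control. Its raw counts over all libraries of a group were 850 in PFAS and 669 in Control, so the fall is in its level relative to other entries. Both miR-486 copies (-2.19 ± 0.90 and -1.96 ± 0.92) and miR-126 (-2.41 ± 1.16) did not pass; miR-486-2 passed with DESeq2 (adjusted p = 0.0288). Of 13 muscle, neural and endocrine entries 2 rose, miR-7-2 (2.22 ± 0.26) and miR-7-3 (2.25 ± 0.27), while miR-7-1, a copy of the same mature miRNA, did not pass (-1.04). The muscle miRNAs miR-1-2 (2.00 ± 0.90) and miR-1-1 (2.06 ± 0.98) did not pass, and they passed without Control replicate 4 (adjusted p = 0.0192 and 0.0462) and with limma-voom (adjusted p = 0.00970 and 0.0126). Of 8 mesenchymal and endothelial entries 1 rose, miR-145 (2.00 ± 0.30). The list of entries that share sequence with other RNA classes had 2 tested members, too few for the list test; miR-12136 and miR-1260b had log2 fold changes of 0.04 ± 0.26 (-0.015 without PFAS replicate 6) and 0.47 ± 0.51. The direction given by camera differed in sign from the median of the members in the let-7 family, the miR-181 family and the 14q32 cluster. The mean was below 0 and the median above 0 in the let-7 family (-0.24 and 0.63), the miR-17-92 list (-0.29 and 0.39) and the miR-23/27/24 clusters (-0.47 and 0.02), and for the miR-17-92 list and the miR-23/27/24 clusters the direction given by camera was up.

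Many abundant entries were high in some libraries of a group and nearly absent from others. Of 150 mature entries with at least 500 CPM in a library of a group, 59 (39.3%) had a gap of at least 16-fold between neighbouring libraries when those of the group were ranked. The low libraries held a median of 18 counts. miR-24-1 ranged from 5.90 to 71239 CPM within Control, and miR-16-1 from 7.37 to 7987 CPM within PFAS, whereas miR-16-2, which gives the same 5p product, ranged from 4820 to 7259 CPM within PFAS. Such a gap was present in 18 of the 97 entries that changed, 2 that rose and 16 that fell. With the entries that had a gap left out, a choice made after seeing the data, 51 rose and 30 fell.

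**Figure D4:**
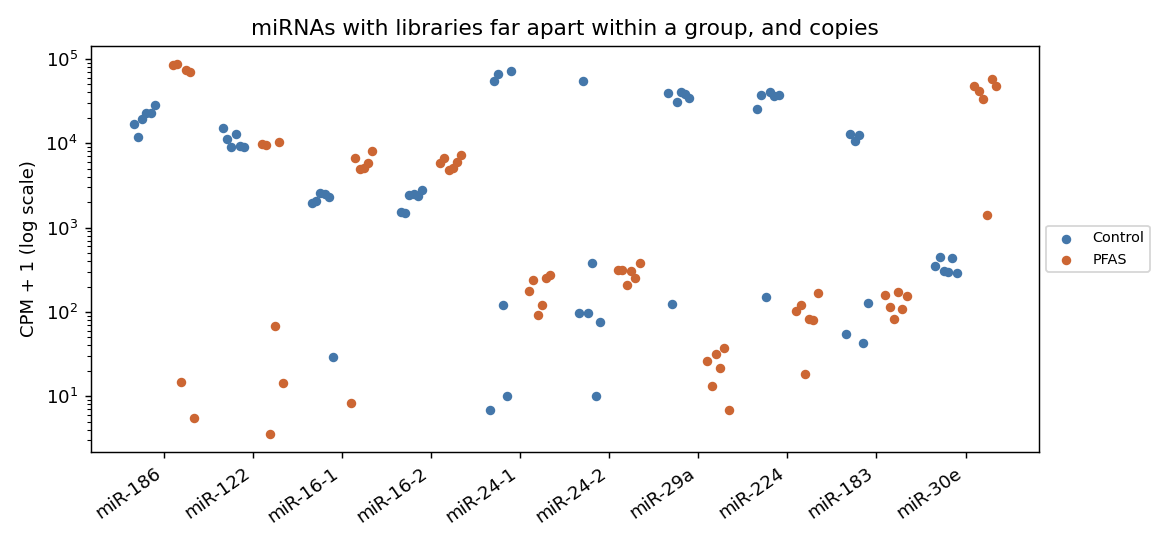
Level in CPM plus 1, on a log axis, of 10 entries in each of the 6 Control (blue) and 6 PFAS (orange) libraries. For all but miR-16-2 at least 1 library lies at least 16-fold from its neighbours in rank, and miR-16-1 shows this in both groups.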

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

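All tests in this part were chosen after the values were seen, except the outlier test itself. In 176 groups of 6 libraries (the named entries on log2 CPM and 3 library measures, per group), 21 had 1 library whose gap to its nearest neighbour was a larger share of the group's range than the 95% critical value of Dixon's test, where chance gives about 8.8 (1 in 20).

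In Control the share of the range was 0.951 for miR-29a (replicate 2 lowest), 0.918 for miR-224 (replicate 3 lowest), 0.928 for miR-29b-2 (replicate 1 lowest), 0.938 for miR-16-1 (replicate 6 lowest), 0.756 for miR-23b (replicate 1 lowest), 0.723 for miR-151a (replicate 1 lowest) and 0.643 for miR-100 (replicate 3 lowest). It was 0.633 for miR-25 (replicate 6 highest) and 0.649 for miR-145 (replicate 5 highest). It was 1 for miR-27a (replicate 1 highest), for miR-522 (replicate 6 highest) and for miR-516a-2 (replicate 1 highest), whose other 5 Control libraries held no count.

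In PFAS the share was 0.665 for miR-891a and 0.661 for miR-224 (replicate 3 lowest in both), 0.858 for miR-30e and 0.702 for miR-30b (replicate 4 lowest in both), 0.766 for miR-15a (replicate 5 lowest), 0.930 for miR-16-1 (replicate 1 lowest), 0.835 for miR-15b (replicate 3 lowest), 0.706 for miR-181b-2 and 0.738 for miR-181d (replicate 2 lowest in both).

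Of these 21 gaps, 8 are among the jumps of at least 16-fold between libraries of a group (miR-29a, miR-224, miR-29b-2, miR-25, miR-16-1 and miR-100 in Control, miR-30e and miR-16-1 in PFAS), and the other 13 are not. Such jumps were present in 64 of 228 cases (an entry in a group), 28 of 93 in PFAS and 36 of 135 in Control. Sampling of reads at low depth is argued against by the median count expected in the low libraries, 2923, where a median of 18 was found. The rule asks for at least 500 CPM in a library, so a high expected count was largely set in advance. Sampling of few original molecules before amplification was not tested. Real differences between wells are argued against by precursor copies with the same mature product: 13 of 18 copy pairs were within 1.5-fold in 1 library and over 16-fold apart in another library of the same group. A candidate explanation is that under a shared row name only 1 arm of a hairpin was kept in each library: entries with a single mature product jumped in 1 of 25 cases and the other mature entries in 63 of 203 (Fisher's exact test, two-sided, p = 0.00361; p = 0.00909 per entry and 0.00314 within strata of group and abundance). The arms themselves are not in the table, so this stays a hypothesis, and no biological explanation other than differences between wells was tested.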

How the results depend on the processing

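Alternatives chosen after seeing the data were thinning all libraries, leaving out entries with a jump, keeping only entries with 1 mature product, merging copies and keeping only mature entries. No paired analysis was possible because the replicate numbers follow accession order and the title numbers are all different, so no number is shared between the groups.

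The number of changed entries was 97 and ranged from 72 to 140 over the settings, apart from 11 (10 rose, 1 fell) among the 47 entries with 1 mature product, where fewer entries were tested. DESeq2 called 122, with 96 of the 97 among them, and thinning left 89, with 76 shared. The number that rose was 95 with limma-voom, 88 with library weights in limma-voom, 79 with no low-count filter and 105 with title numbers 6 apart summed. The number that fell was 31 with no low-count filter, 20 and 19 with title numbers 1 to 6 and 7 to 12 only (3 libraries per group) and 30 with jump entries left out. Leaving out each replicate gave 40 to 85 that rose and 32 to 48 that fell. Other scalings gave 52 or 53 that rose, with the median log2 fold change between -0.04 and 0.02 against -0.08. That median was -0.39 with thinning, 0.66 with limma-voom, 0.31 with title numbers 6 apart summed, 0.24 with mature entries only and 1.84 with no filter, and small fold changes move with it. Leaving out a Control library moved it to between 0.13 and 0.28, and leaving out a PFAS library to between -0.18 and 0.21. The cause of the other differences was not tested.

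No list passed in camera except with no low-count filter. There 3 lay below the other entries (the miR-30 family, adjusted p = 0.0289, and the blood cell and the liver injury lists, 0.0376), and none of these with an estimated correlation (adjusted p = 0.269). The median log2 fold change of all entries was 1.84 in that setting, so this does not show that the 3 lists fell. The share of the most abundant entries passed for miR-146a, the entry with the highest mean over the 12 libraries but not in Control (15.4 percentage points), and for the 50 most abundant (1.15), and leaving out each replicate gave 3.42 to 5.96. Differences in totals and in detected entries kept their direction and passed in all settings run, but the difference in detected entries was 61.9 with at least 5 counts against 295.2 with at least 1.

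Of 85 named entries, 48 were called, 28 of them in every setting that tested them, and no called entry reversed. Over entries and settings, 98 calls were lost and 51 gained. The lost calls, with the number of settings and the highest adjusted p, were those of let-7a-1 (17, 0.299), let-7a-2 (1, 0.117), miR-151a (2, 0.122), miR-183 (4, 0.282), miR-192 (1, 0.0622), miR-197 (2, 0.116), miR-19b-2 (6, 0.328), miR-200b (1, 0.122), miR-200c (5, 0.183), miR-203a (18, 0.473), miR-21 (1, 0.185), miR-224 (1, 0.112), miR-24-1 (6, 0.487), miR-29a (2, 0.201), miR-29b-2 (1, 0.117), miR-30b (11, 0.229), miR-30c-1 (11, 0.395), miR-30e (2, 0.582), miR-369 (3, 0.149) and miR-451a (3, 0.313). Uncalled entries reversed as follows, with log2 fold changes. With limma-voom, miR-186 was at -2.16, let-7a-3 at 0.066, miR-24-2 at 0.36, miR-320c-1 at 0.068, miR-320c-2 at 0.046 and miR-493 at 0.21; with library weights, miR-92a-2 at -0.029, miR-186 at -2.15, let-7a-3 at 0.33, miR-24-2 at 0.23, miR-320c-1 at 0.13, miR-320c-2 at 0.022 and miR-493 at 0.15. With a minimum count of 50, miR-92a-2 was at -0.15, miR-128-2 at -0.13, miR-15b at -0.077, miR-320d-1 at -0.13 and miR-12136 at -0.16; with thinning, miR-92a-2 at -0.35, miR-128-2 at -0.35, miR-15b at -0.25, miR-320d-1 at -0.26, miR-1323 at -0.18 and miR-12136 at -0.38. With no filter, miR-423 was at 0.070, miR-320c-1 at 0.16 and miR-320c-2 at 0.29. With title numbers 1 to 6, let-7a-3 was at 0.39, miR-15b at -0.026 and miR-320d-1 at -0.41; with 7 to 12, miR-423 at 0.038, miR-24-2 at 1.84, miR-320c-1 at 0.61, miR-320c-2 at 0.43 and miR-516a-2 at -0.38; with those 6 apart summed, miR-423 at 0.075, miR-320c-1 at 0.076 and miR-320c-2 at 0.32. miR-320c-2 was also at 0.092 with DESeq2, 0.089 with RLE, 0.13 with TMMwsp, 0.057 with total counts, 0.14 without the most abundant entry, 0.073 with a minimum count of 3 and 0.012 with the title ranges as a term. Leaving out each replicate gave -0.077 to 0.36 for miR-92a-2, -0.27 to 0.13 for miR-423, -0.049 to 0.38 for miR-128-2, -2.00 to 0.59 for let-7a-3, -3.66 to 0.29 for miR-25, -4.97 to 1.38 for miR-24-2, -0.25 to 0.36 for miR-320c-1, -0.17 to 0.92 for miR-320d-1, -0.069 to 0.38 for miR-320c-2 and -0.015 to 0.35 for miR-12136. The median of all entries also moved between these settings, as given above, and small fold changes move with it. Beyond this the cause was not tested.

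Depth limits the low entries most: 3 counts are 6.91 to 11.4 CPM in a Control library and 1.16 to 2.46 CPM in a PFAS library.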

Other observations

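Only the test of chance behind the number of changed entries was chosen before the results were seen. Of 33 miRNAs with several tested precursors, 22 had log2 fold changes within 1.5-fold of each other, but only 4 of these 22 had a copy that changed (miR-101, miR-16, miR-19b and miR-6511b, of which both copies fell, -2.10 and -1.88). Both copies of miR-196a, transcribed from HOX clusters, rose (3.32 and 3.94). In 9 miRNAs some copies changed and others did not pass. In 3 miRNAs (9.09%) the copies differed by more than 16-fold: let-7a (-2.83 to 2.04), miR-26a (-3.77 to 3.02) and miR-29b (-6.74 to -2.26). A common level reported by all copies is argued against by the 13 of 18 copy pairs that were within 1.5-fold in 1 library and over 16-fold apart in another of the same group.

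The number of changed entries exceeded what other groupings gave. Of 100 splits of the 12 libraries into 6 and 6, drawn at random and including the real 1, only the real split gave as many as 97. The highest of the others gave 3, which argues against chance among libraries taken as independent. If the libraries are repeats of fewer cultures, these splits do not exclude chance between cultures. The 5.10-fold difference in totals is argued against as the whole cause, since 89 entries changed with every library thinned to the smallest total. Keeping 1 arm per library is argued against as the whole cause, since 23.4% of the 47 entries with a single mature product changed (10 rose, 1 fell). Of the 10, 5 had no Control count, and without these 5 the share was 14.3% (6 of 42, exact binomial test against 5%, one-sided, p = 0.0174). That 5% is the adjusted p threshold, not a measured rate of calls among unchanged entries, and entries are not independent. The list was not checked against a miRNA database, so the argument holds only as far as that list is right. For the entries that fell, keeping 1 arm per library stays open. Of the entries with a single mature product 2.13% fell, against 15.7% of the other mature entries (Fisher's exact test, two-sided, p = 0.0108). Entries were not matched for Control level, and the 5 single-product entries with no Control count could not fall, so this test cannot settle it. Large falls such as that of miR-30d may reflect a different arm in each group. So may rises such as those of miR-192, miR-27a and miR-30e, which are not on the single-product list. An effect of PFAS stays untested beside this.

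Control libraries lacked many miRNAs that every PFAS library held: 42 entries had no count in all 6 Control libraries and counts in all 6 PFAS libraries, and 0 had the reverse. The difference in totals is argued against as the whole cause, since 62.5% of the 42 kept a count in all 6 PFAS libraries after thinning to equal depth. Among entries with a group mean of 5 to 20 counts at equal depth, zeros made up 51.1% ± 5.66 of the Control values and 5.56% ± 0.939 of the PFAS values (SD, n = 6 each, difference 45.5 percentage points, exact permutation p = 0.00216, two-sided). This is consistent with fewer original molecules behind the Control counts, which could also stand behind part of the 10 entries that rose from no Control count. Whether exposed cells released more vesicle RNA, or more of it reached the libraries, was not tested, because the table holds no measure of input.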
